A study of Mus musculus with 24 samples.

How the data were processed

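Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in 4 hindlimb muscles of male FVB/NJ mice, an inbred strain. Soleus and vastus intermedius were named slow-biased by the study (richer in slow-contracting, oxidative fibres), and gastrocnemius and vastus lateralis fast-biased. Each muscle was taken from 3 adult mice (P56) and from 3 litters at embryonic day 18.5 (E18.5), which gave 24 libraries in 8 groups of 3. All 4 muscles of a replicate came from the same adult animal or the same litter, and an E18.5 replicate pooled the muscles of male embryos of 1 litter, per the labels' protocols. The protocols also gave the adult mice an age of 3 to 4 months, which differs from P56, and the age was not settled here. Nuclei were isolated from undigested tissue, per the labels' protocols, so every cell type of a muscle could contribute.

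The authors deposited 1 peak list per library, and each list gives only chromosome, start and end of each peak on the mm10 build, with no score, count or signal. Peaks were called per library and not on pooled replicates, as the files show. Per the submitters' processing notes, the tools included FastQC 0.11.5, Trimmomatic 0.39.0, Bowtie2 2.4.4, SAMtools 1.14.0, Picard, MACS2 2.1.1 and bedtools 2.25.0. The thresholds, the shift of reads for the transposase and the read depths are not given in the sources used here, so the length of a list was the only measure of depth. No pair of lists was identical (0 of the pairs). A peak call is a yes or no for a library: it carries no amount of accessibility, and a missed call does not show closed chromatin.

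The peaks on chromosomes 1 to 19, X and Y of all 24 lists were merged into regions with code written for this purpose, by the rule that bedtools merge uses, and regions called in at least 2 libraries were kept. A library called a region when a peak overlapped it by at least 1 bp. Gene positions came from the RefSeq annotation of GRCm38.p6, the assembly of mm10, and 34610 protein-coding and lncRNA genes were used. That table gave gene starts and ends without strand or exons, so regions were classed as within 1 kb of a gene end, inside a gene or between genes, and exons, introns, UTRs and promoters were not told apart. A gene's locus was its body plus 10 kb on each side. Loci of neighbouring genes can overlap, so a region can count for more than 1 gene, as between Myh2 and Myh1 and between Myh4 and Myh8.

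The design set before the data were examined took the same number of the best-scored peaks from each list and named the full lists as the choice if no score was present. The lists held no score, so the full lists were used. Also fixed before the data were examined were the gene lists, the rule for named genes, the tests of regions and of lists, and all alternatives except 1. Per region, Fisher's exact test (two-sided) compared the libraries calling it, 12 adult against 12 E18.5 or 6 slow-biased against 6 fast-biased within a stage. Benjamini-Hochberg adjustment ran over the regions whose number of calls could pass 0.05 in the exact test, and 0.05 was the threshold. Slow-biased and fast-biased libraries of both stages were compared by an exact conditional test stratified by stage. The 12 libraries of a stage came from 3 animals or litters, so the p-values per region for the stages are too small. Regions called in every library of one side and in 0 of the other are given beside them. Between single muscles (3 against 3) no region can reach a p under 0.1, and only such separated regions were counted.

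The 25 gene lists held 416 names, of which 414 matched the annotation. The 2 that did not, Bmal1 and Redd1, are other names of Arntl and Ddit4. Of the lists, 15 were gene programs: slow fibre, fast fibre, embryonic and neonatal muscle, fibre type regulators, oxidative metabolism, glycolytic, myogenic progenitor, limb patterning, Hox, neuromuscular junction, extracellular matrix, cell cycle, circadian clock, glucocorticoid and atrophy, and immediate early genes. The other 10 were cell type markers: fibro-adipogenic cells and fibroblasts, tendon, cartilage and bone, endothelium, smooth muscle and pericytes, immune cells, Schwann cells and neurons, adipocytes, erythroid cells and heart muscle. For each list, the share of libraries calling a region was averaged over the regions of each locus and then over the genes. The difference between the sides, in percentage points, was set against 10000 random lists of the same size matched on the number of regions in the locus (a two-sided permutation test, smallest p 0.0001), adjusted over 75 tests. The difference between the adult and the E18.5 effect was tested the same way, adjusted over the 25 lists. Both tests treat genes, not animals, as the unit. Labels of fibre bias were also permuted within animals (exact, smallest p 0.00926).

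The text names by rule 18 fixed loci, up to 12 listed genes per direction with the most regions past the threshold (adjusted p under 0.05 between stages, unadjusted p under 0.05 for fibre bias), and up to 5 regions per direction. Genes named outside this rule were chosen after their values were seen: those of the locus tests, of the animal means and of chromosome Y. Similarity of a pair of libraries was the Jaccard index of their called regions. It was tested by permuting muscle labels within animals, and, in place of the planned arrangement, animal labels within muscles (exact, one-sided). Chosen after the data were seen were the exact permutation test of each locus within a stage (two-sided, 924 arrangements of 6 against 6 libraries, smallest p 0.00216, adjusted over 414 genes), the same within animals and over a list alone, the separation of animal means between stages, and the permutation within animals of a list's stage difference. The rule that says when a named locus changed direction under an alternative was also settled after values were seen. The planned motif search was not run, since no genome sequence was used here.

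The shared replicate number stands for a shared animal or litter, per the labels' protocols, so it pairs the 4 muscles. The correlation of deviations from the group means averaged 0.0127 for adult libraries of the same animal and -0.00633 for other pairs, and 0.0541 and -0.0271 at E18.5. The deviations of the 3 libraries of a group sum to 0. The value of other pairs therefore follows from that of the same animal and is not separate support for the pairing. In each stage 10 of 12 libraries correlated best with their own animal. The file labels give replicate 1 another date than replicates 2 and 3 in each stage, and no date is shared by the stages, so date and stage cannot be told apart. Values without replicate 1 are the values within a date.

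The tests of regions were tried on simulated calls and the tests of lists on random lists. The tests of similarity, of single loci, of muscle pairs and within animals were not tried in this way. Simulated calls were shuffled over the libraries of each region, so they held no likeness between libraries of the same animal. Between stages, with 170248 regions tested, 200 of 200 regions separated completely were recovered, 34.5% of those called in 0.9 against 0.1 of libraries, and 4% of those called in 0.75 against 0.25. With 6 against 6 libraries, 0 of 200 completely separated regions passed the adjusted threshold, since about 2084 (adult) or 2161 (E18.5) such regions would be needed. The zero counts of adjusted calls between slow-biased and fast-biased muscles within a stage therefore do not show that regions were alike. Of 200 random lists of 20 genes, 4.5%, 5.5% and 3.5% had p under 0.05 in the stage, adult and E18.5 comparisons. They were set against random genes of the same libraries, so shares near the threshold follow from the design. These shares do not measure false calls that come from animals, list length or date.

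Alternatives changed 1 choice at a time, except the animal as a block. Those of calls were the first 57666 peaks of each list and a call that covers at least 50% of the region. Those of regions were no minimum or at least 4 libraries per region, regions up to 2000 bp, autosomes, and adjustment over all regions. Others were loci without a flank or with 50 kb, gene ends within 2.5 kb, and the pairs of muscles apart. Each animal or litter was also left out in turn. With the animal as a block, labels of fibre bias were permuted within animals. The gene lists were then no longer compared with random lists, so more than 1 choice changed. The same number of peaks from each list (115333, the shortest) was added after the files showed that early peaks of a list were shared more. Peaks in the first 10% of a list were shared by 20.4 to 23.4 libraries on average and those in the last 10% by 4.81 to 9.24. The order was taken to follow strength, which could not be checked without a score, and the first 57666 peaks rest on this too. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.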

Results

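The 24 peak lists described open chromatin in soleus, vastus intermedius, gastrocnemius and vastus lateralis of 3 adult mice and 3 litters at E18.5. List length ran from 115333 peaks in adult vastus intermedius 1 to 228137 in E18.5 soleus 2. In the adult, lists held 171485 ± 21898 peaks in gastrocnemius (SD, n = 3), 176761 ± 31943 in soleus, 130608 ± 15031 in vastus intermedius and 187519 ± 31634 in vastus lateralis. At E18.5 they held 174093 ± 38310, 159426 ± 59689, 174158 ± 31025 and 163747 ± 14423 in the same order. Slow-biased lists were -25818 peaks apart from fast-biased ones in the adult (exact permutation within animals, two-sided p = 0.157) and -2128 apart at E18.5 (p = 0.935). Adult and E18.5 animals differed by -1263 peaks on average (exact permutation p = 1, where 0.1 is the smallest possible with 3 against 3).

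**Figure D1:**
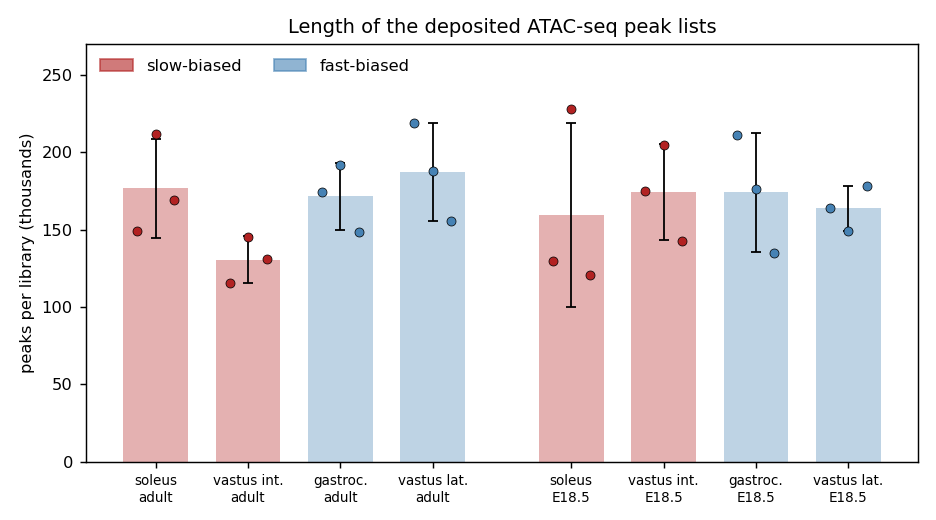
Peaks in each deposited list (vertical axis, peaks per list) for the 3 libraries of each of the 8 groups (horizontal axis), with points for libraries, bars for group means and error bars for the SD. Adult vastus intermedius had the lowest group mean (130608 ± 15031) and E18.5 soleus the widest spread (SD 59689).

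Merging the lists gave 931444 regions, of which 471776 were called in 1 library only, and 459668 regions with a median width of 745 bp were kept. All 24 libraries called 18296 regions. Of these, 59.1% lay within 1 kb of a gene end, against 17.1% when the genes were moved by 50 kb. All 12 adult libraries called 23298 regions and all 12 E18.5 libraries 34274.

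Libraries of the same stage and muscle shared only part of their regions. The Jaccard index averaged 0.336 between adult libraries (0.275 to 0.4), 0.408 between E18.5 libraries (0.351 to 0.502) and 0.324 across stages (0.274 to 0.372). Adult libraries of the same muscle from different animals had an index of 0.345 and those of different muscles and animals 0.332 (exact permutation, one-sided p = 0.00347). At E18.5 the values were 0.404 and 0.401 (p = 0.139), and with the same number of peaks from each list the same-muscle index was higher by 0.0117 (exact permutation p = 0.00174). Libraries of the same adult animal had 0.339 against 0.332 (exact permutation p = 0.00926), and with autosomes alone the difference was 0.00378 (p = 0.0694). Libraries of the same litter had 0.425 against 0.401 (exact permutation p = 0.0139). Within litters the mean was 0.485 in litter 1, which has its own date, 0.418 in litter 2 and 0.371 in litter 3. Without adult 3 the difference by muscle in the adult was 0.00892 (exact permutation p = 0.125), and with any animal left out the differences by animal or litter could not go below p = 0.125.

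**Figure D2:**
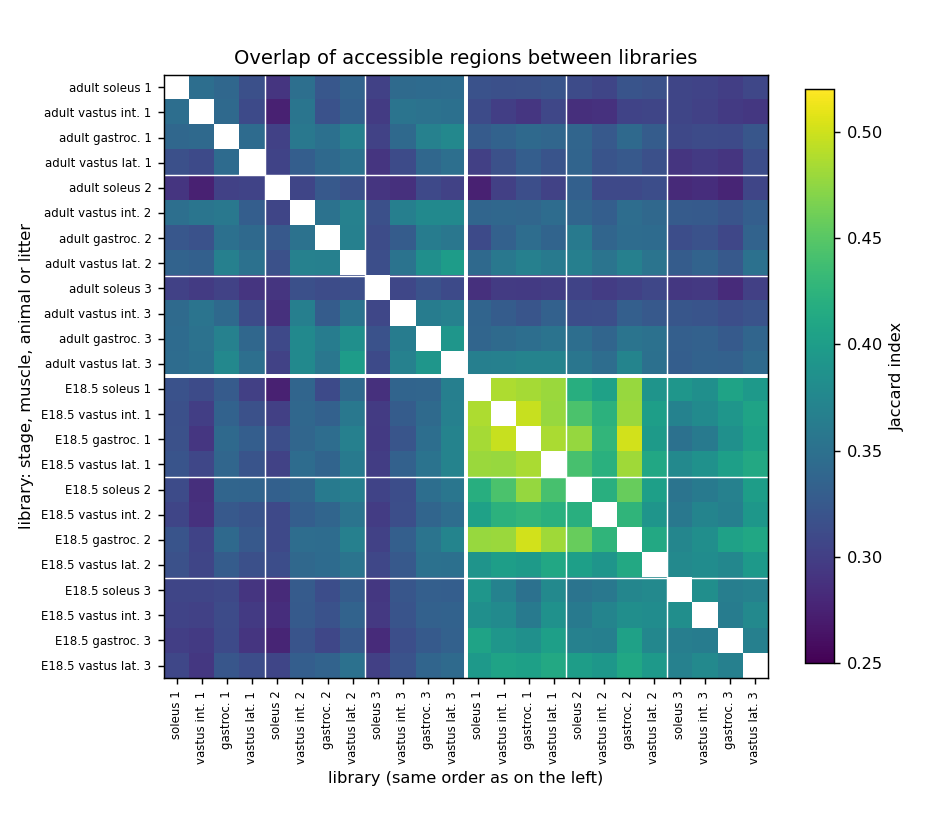
Jaccard index (colour scale, shared regions as a fraction of the regions called in either) for each pair of the 24 libraries, ordered by stage and then by animal or litter on both axes. Pairs of E18.5 libraries averaged 0.408, adult pairs 0.336 and pairs across stages 0.324.

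The comparison of adult with E18.5 muscle asked which loci differed in open chromatin between late foetal and mature muscle. The locus of Myh4, the fastest myosin heavy chain (chromosome 11, 67237812 to 67260447, mm10), held 7.17 ± 1.28 called regions per library in the adult and 0.583 ± 0.289 at E18.5 (SD over n = 3 animals or litters). In the adult 5 of its regions were called more often (Fisher's exact test, adjusted p under 0.05). Myl1, the fast alkali myosin light chain, held 7.25 ± 0.901 against 1.25 ± 1 with 3 such regions. In the other direction Col3a1, a fibrillar collagen, held 3.58 ± 1.04 against 9.58 ± 1.04 with 2 regions higher at E18.5, and Col1a2, a chain of type I collagen, 2.42 ± 1.13 against 7.58 ± 1.63 with 3. Across the genome 2630 regions were called more often in the adult and 7741 at E18.5, of 170248 tested (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). The counts depend on the processing: 4106 and 11209 with the same number of peaks from each list, 6270 and 13032 with the first 57666 peaks, and 1632 and 6832 with calls that cover 50% of a region. With the full lists, 106 were called in 12 of 12 adult and 0 of 12 E18.5 libraries and 298 the other way round. Libraries of one animal are not independent, and date and stage cannot be told apart.

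Genes of the mature fibre were called more in the adult. For the fast fibre list the mean share of libraries calling a region was 46.1% in the adult and 37.6% at E18.5, a difference of 8.56 percentage points where random lists averaged -3.19 (permutation against random lists, two-sided, adjusted p = 0.00125). Tests against random lists treat genes, not animals, as the unit, here and for the lists below. With 3 adults against 3 litters no permutation of animals can go below p = 0.1. The fast fibre list had 12 regions higher in the adult and 3 at E18.5, and 15 and 6 adjusted over the list alone. Myh1, another fast myosin, held 5.42 ± 1.26 regions against 0.917 ± 0.629 (n = 3 animals or litters) with 1 region higher in the adult. Its locus overlaps that of Myh2, so the 2 loci share regions and are not separate results. Tnnt3, the fast troponin T, held 5.17 ± 0.629 against 6.5 ± 0.866 with 2 higher at E18.5. Tnni2 and Atp2a1, the fast troponin I and the fast calcium pump, had no region past the threshold (3.5 against 3.33 and 6.42 against 7.17). The slow fibre list differed by 4.47 points (38.8% against 34.3%, random mean -3.4, adjusted permutation p = 0.00167), with 7 and 5 regions, or 9 and 6 adjusted over the list alone. Its fixed loci showed little of this: Myh7, the slow myosin, held 8.58 ± 0.946 against 7.83 ± 1.88, Atp2a2 9.33 against 9, Tnnt1 6 against 6.08 and Myl3 4.17 against 4.58. None of these 4 had a region past the threshold. Tnni1 and Myl2 had 1 region higher in the adult each (9.17 against 9.67 and 7.67 against 7.75), and Fhl2 had 3 higher at E18.5 (8.5 against 11.3). The net direction of Tnni1, Myl2 and Tnnt3 turned with the first 57666 peaks of each list, and that of Tnni1 also with 50% cover and with 50 kb flanks. Myh2, the type IIa myosin placed on the slow list, held 5.92 ± 0.382 against 1.67 ± 1.04 with no region past the threshold.

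The glycolytic list differed by 6.58 points (random mean -3.32, adjusted permutation p = 0.00125), with 11 regions higher in the adult and 2 at E18.5 (12 and 3 adjusted over the list alone). Gys1, muscle glycogen synthase, held 8.75 against 6.58 regions with 3 higher in the adult. The oxidative list differed by 7.23 points (random mean -3.27, adjusted permutation p = 0.00125; 22 and 7 regions, 32 and 9 adjusted over the list alone). Ppargc1a, a coactivator of mitochondrial genes, held 35.4 ± 7.3 against 22 ± 6.41 regions (3 higher in the adult, 2 at E18.5). Esrrg, an oestrogen-related receptor, held 43.2 ± 5.17 against 31.9 ± 4.73 (4 and 2), and Ppargc1b 25.2 against 22.7 (3 and 2). The glucocorticoid and atrophy list differed by 5.41 points (random mean -3.32, adjusted permutation p = 0.00167; 11 and 2 regions, 17 and 2 adjusted over the list alone). The transcription factor Zbtb16 held 42 ± 2.78 against 24.7 ± 7.14 regions, with 4 higher in the adult. Fibre type regulators differed by 2.91 points (random mean -3.01, adjusted permutation p = 0.00225; 24 and 14 regions, 35 and 21 adjusted over the list alone). Among them Sox6, a repressor of slow genes in fast fibres, held 33.7 ± 1.42 against 19.8 ± 4.26 regions and Tbx15, found in glycolytic fibres, 14.7 ± 0.764 against 10.6 ± 1.51, each with 3 regions higher in the adult. Nfix, which promotes the foetal myogenic program, had 4 higher in the adult (27.8 against 25), Eya4 had 1 and 4 (10.9 against 11.9), and Tead1 2 and 3 (43.6 against 42.3). The clock receptor Rora had the most regions higher in the adult of any listed gene, 9 against 1 (88.9 ± 2.93 against 55.3 ± 14.8). Its locus held 277 regions, against 14 at Myh4. Counts past the threshold were not scaled to the size of a locus, so this ranking favours long genes.

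Extracellular matrix genes were called more at E18.5 (adult minus E18.5 -9.99 points, random mean -2.82, adjusted permutation p = 0.00167), with 3 regions higher in the adult and 22 at E18.5, or 5 and 32 adjusted over the list alone. Fibrillin Fbn1 held 22.5 ± 1.39 against 33.5 ± 7.37 regions with 3 higher at E18.5, and Postn and Col12a1 had 2 each (2.08 against 4.5 and 4.83 against 13.9). The heart muscle list differed by -11.7 points (adjusted permutation p = 0.0211, 0 and 3 regions). This call was lost in 9 alternatives, among them the same number of peaks from each list (adjusted permutation p = 0.358) and leaving out adult 3 (adjusted p = 0.0755) or litter 1 (adjusted p = 0.11). The embryonic and neonatal list differed by -7.74 points (adjusted permutation p = 0.0865), with 2 regions higher in the adult and 12 at E18.5. In it the embryonic myosin Myh3 held 7.25 ± 0.661 against 7.25 ± 1.39 regions and the neonatal Myh8 2.08 ± 1.38 against 1.92 ± 0.382, with 1 region higher at E18.5 in each. Limb patterning genes differed by -7.49 points (adjusted permutation p = 0.14), with 4 and 10 regions. There Prrx1, expressed in limb mesenchyme, held 9.42 against 5.33 with 3 higher in the adult and 1 at E18.5, while the homeobox gene Meis2 held 8.33 against 13.1 with 3 higher at E18.5. Met, the receptor that migrating muscle progenitors use, had 3 higher at E18.5 (8.67 against 11.2), as did Col14a1 (10.1 against 16.6) and Tcf7l2 (32.5 against 40.6) of the fibroblast list.

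The net direction of regions past the threshold turned in at least 1 alternative at Tead1, Ppargc1b, Prrx1 and Myh8. At Myh8 it turned with 50 kb flanks, which take in all of Myh4, so this does not show a change at Myh8 itself. The other lists did not pass the test between stages: myogenic progenitor (-5.52 points, adjusted permutation p = 0.658), Hox (-6.89, 0.408), neuromuscular junction (-6.11, 0.408), cell cycle (-5.27, 0.694), circadian clock (-2.35, 0.855) and immediate early genes (-1.12, 0.622). The same held for markers of fibro-adipogenic cells and fibroblasts (-4.34, 0.855), tendon (-5, 0.855), cartilage and bone (-5.23, 0.855), endothelium (-0.298, 0.609) and smooth muscle (-2.82, 0.936). It held too for immune cells (-6.06, 0.667), Schwann cells and neurons (-8.14, 0.408), adipocytes (-0.314, 0.622) and erythroid cells (-4.34, 0.922). Region counts changed with single animals or litters left out. Without adult 1, litter 1, litter 2 or litter 3, the adult-higher count was 1418, 1622, 1416 or 1503, and without adult 1, litter 1 or litter 2 the E18.5-higher count was 4037, 2917 or 4239, while without litter 3 it was 9043.

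**Figure D3:**
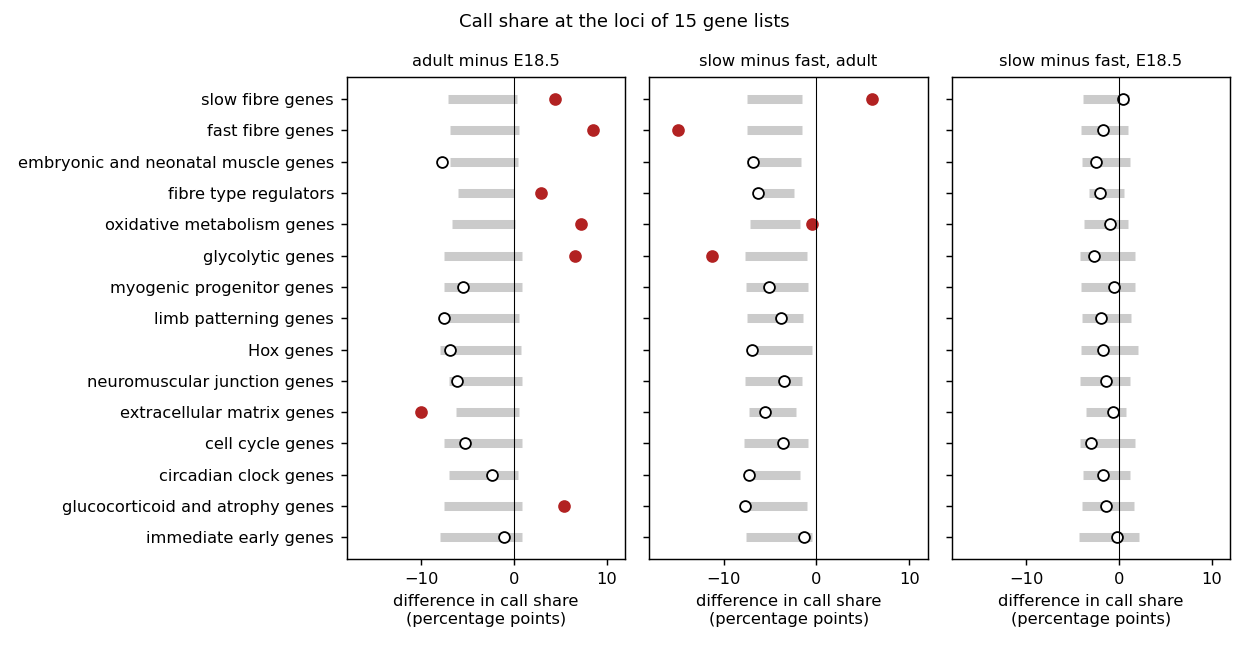
Difference in the share of libraries calling the regions of each gene list (horizontal axis, percentage points) for the 15 gene program lists (vertical axis), with grey bars for the matched random lists (mean ± 2 SD) and filled points for lists past the adjusted threshold. Between stages 7 of the 15 were filled, in adult slow against fast muscles 4, and in E18.5 muscles 0.

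Single regions stood at the extreme of the stage comparison, called in 12 of 12 libraries of one stage and 0 of 12 of the other (Fisher's exact two-sided p = 7.4e-07, adjusted p = 0.000312). In the adult such regions lay on chromosome 17 at 44214643 to 44216065 inside Clic5 and on chromosome 7 at 112741128 to 112742442 inside Tead1, a partner of YAP. Others lay on chromosome 1 at 189959926 to 189961215 (37431 bp from Smyd2), on chromosome 9 at 44474006 to 44475069 (7669 bp from Bcl9l) and on chromosome 16 at 24176853 to 24178074 (187987 bp from Bcl6). Those of E18.5 lay on chromosome 1 at 24553495 to 24554361 inside Col19a1 and on chromosome 10 at 120616077 to 120617523 (139608 bp from Hmga2, a growth regulator of embryonic tissue). Others lay on chromosome 4 at 64058154 to 64059622 in a lncRNA gene 11139 bp from Tnc, which encodes tenascin C, on chromosome 14 at 25185351 to 25187380 and on chromosome 9 at 100194091 to 100195397. With calls that cover 50% of a region, the Clic5 region had an adjusted p of 0.0992 by Fisher's exact test and the Tead1 region 0.0541. Regions higher in the adult lay within 1 kb of a gene end in 10.2% of cases, inside a gene in 63.2% and between genes in 26.6%, and those higher at E18.5 in 12.5%, 46.5% and 41%. The difference near gene ends (Fisher's exact two-sided p = 0.00154) was lost without litter 1 (p = 0.729), litter 2 (p = 0.803) or litter 3 (p = 0.251), and with a distance of 2.5 kb (p = 0.0944).

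The comparison of slow-biased with fast-biased adult muscles asked which loci follow fibre type. The locus of Myh4 held 3.5 ± 3.08 called regions in slow-biased and 10.8 ± 1.83 in fast-biased libraries (SD, n = 6 each; exact permutation, two-sided p = 0.00433, adjusted p = 0.112). Sox6 held 26.5 ± 4.55 against 40.8 ± 6.24 and Rora 69.5 ± 7.09 against 108 ± 14.4, both at the smallest possible exact p of 0.00216 (adjusted p = 0.0896). On the slow side Atp2a2, the slow and cardiac calcium pump, held 11.8 ± 2.04 against 6.83 ± 1.72 (exact p = 0.00433). Myoz2, a slow-fibre protein of the Z-disc, held 5 ± 1.55 against 1.33 ± 1.37 (exact p = 0.00866, adjusted p = 0.133). Ppargc1a held 43.3 ± 6.44 against 27.5 ± 10.6 (exact p = 0.0195, adjusted p = 0.208). None of the 414 loci passed adjustment. At unadjusted exact p under 0.05 there were 6 higher in slow-biased and 53 higher in fast-biased muscles. These tests compare with 0 and were not scaled to list length. Slow-biased lists held 153684 peaks on average and fast-biased ones 179502, and random lists too were called less in slow-biased muscles. No share over all genes is given here, so the excess on the fast side cannot be laid to the listed genes.

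The regions of the fast fibre list were called in 38.7% of slow-biased and 53.6% of fast-biased libraries on average, a difference of -14.9 points where random lists averaged -4.49 (permutation against random lists, two-sided, adjusted p = 0.00125). It passed when fibre bias was permuted within animals (exact p = 0.00926, the smallest possible, adjusted p = 0.0331). That test compares with 0, though random lists averaged -4.49 points. At this smallest p a list can pass adjustment over the 25 lists only if several lists reach it. The pass is therefore not separate support for a difference particular to fast fibre genes. By muscle the share was 35.7 ± 1.22% in soleus, 41.6 ± 0.555% in vastus intermedius, 51.9 ± 3.93% in gastrocnemius and 55.3 ± 3.53% in vastus lateralis (SD, n = 3). Adjusted over the list alone, 4 of its regions and 9 of its loci were higher in fast-biased muscle. At the smallest exact permutation p of 0.00216 were Actn3, the fast-fibre actinin (3.67 ± 0.516 against 7 ± 0.894 regions), Casq1, the fast calsequestrin (4.17 ± 0.983 against 7.17 ± 1.17), Ampd1 (4.67 ± 1.21 against 8.83 ± 1.17) and Ryr1, the calcium release channel (25 ± 5.37 against 34.8 ± 2.56). The others were Mybpc2, Myh4, Tpm1, Mylpf and Myoz1. These tests permute libraries freely; permuted within animals, 5 loci passed over the list alone (Actn3, Casq1, Ampd1, Ryr1 and Mybpc2, exact p = 0.00926, adjusted p = 0.037). The slow fibre list differed the other way, by 5.93 points where random lists averaged -4.51 (adjusted permutation p = 0.00125; 41.8% against 35.8%), in 3 of 3 animals. Permuted within animals its p was 0.0556 (exact, adjusted p = 0.0992), and adjusted over the list alone 0 of its loci and 3 unadjusted (Atp2a2, Myoz2 and Csrp3) were higher in slow-biased muscle. The slow myosin Myh7 held 10.2 ± 2.48 against 7 ± 4.38 regions and Myh2 7 ± 2.19 against 4.83 ± 1.6 (exact permutation p = 0.186 and 0.104). Within 1 date, without adult 1, the fast list lay -11.2 points and the slow list 9.62 points from random lists (adjusted permutation p = 0.00187 for each).

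**Figure D4:**
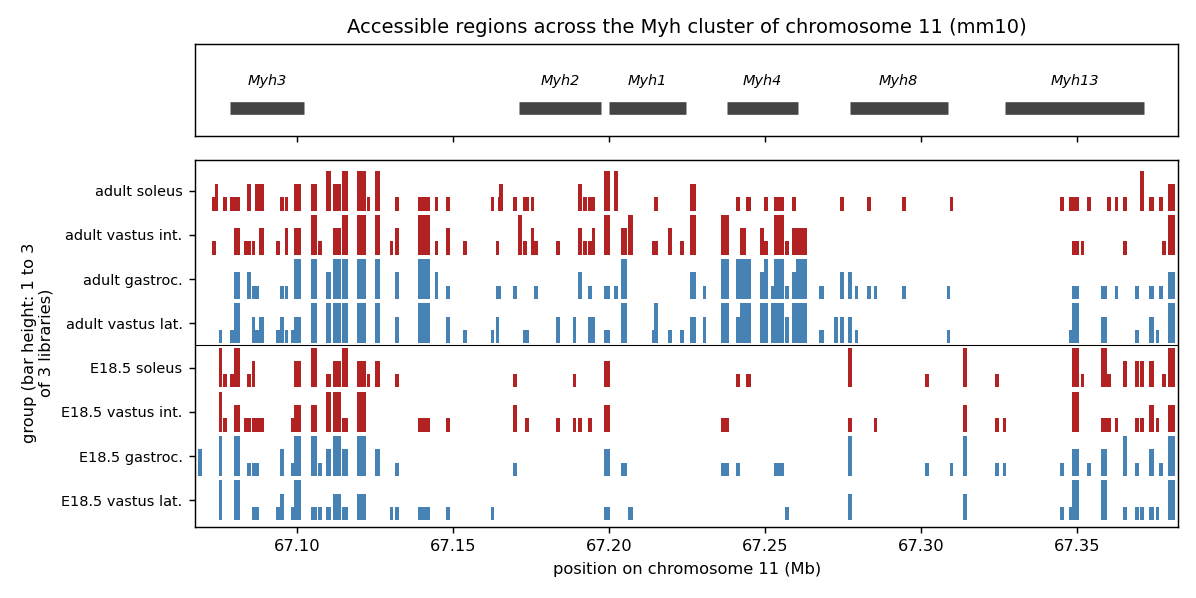
Called regions along the cluster of skeletal myosin heavy chain genes on chromosome 11 (horizontal axis, position in mm10), with bar height the number of the 3 libraries of a group that called a region and narrow regions widened to be visible. Over Myh4 the adult fast-biased libraries held 10.8 ± 1.83 called regions, the adult slow-biased ones 3.5 ± 3.08 and E18.5 libraries 0.583 on average.

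The glycolytic list differed by -11.2 points (random mean -4.35, adjusted permutation p = 0.00125; within animals adjusted exact p = 0.0331). With autosomes alone the list lay -2.31 points from random lists and the call was lost (adjusted permutation p = 0.557). The named genes this leaves out were Pgk1, phosphoglycerate kinase (1 ± 0 against 2.67 ± 0.516 regions), and Phka1, a subunit of phosphorylase kinase (3.33 ± 0.816 against 8 ± 3.29). Adjusted over the list alone, 2 of its regions were higher in fast-biased muscle. The oxidative list differed by -0.533 points where random lists averaged -4.45 (adjusted permutation p = 0.0225), and permuted within animals against a difference of 0 its exact p was 0.769. Its call was lost in 6 alternatives against random lists: without adult 1 (adjusted permutation p = 0.576) or adult 2 (adjusted p = 0.051), with calls that cover 50% of a region (0.0755), with no minimum of libraries (0.0544), with regions up to 2000 bp (0.332) and with the gene body alone (0.164). Permutation within animals compares with a difference of 0 and not with other genes. It also called the lists of embryonic and neonatal genes (-6.8 points), fibre type regulators (-6.31), myogenic progenitors (-5.12), the circadian clock (-7.25) and glucocorticoid and atrophy genes (-7.71), each with an adjusted permutation p of 0.0331. Adjusted over the list alone, 5 regulators (Camk4, Hdac4, Sox6, Nr4a1 and Ppp3ca) and 4 clock genes (Rora, Npas2, Nr1d2 and Bhlhe41) were higher in fast-biased muscle. So were 1 limb gene (Lhx2), 1 glycolytic gene (Pgk1) and 2 fibroblast genes (Smoc2 and Tcf7l2). All of these calls came from permuting libraries freely, against a difference of 0 and not against other genes. They were lost with permutation within animals (lowest adjusted exact p = 0.0519 for regulators, 0.088 for clock genes, 0.0926 for the limb and glycolytic lists and 0.139 for fibroblasts). The smallest exact permutation p within animals is 0.00926, so several loci of a list must reach it before any passes. The loss can come from this limit. Hdac4, which represses Mef2, held 41.7 ± 5.61 against 55.3 ± 2.16 regions and Camk4 6.83 against 10.5, both at exact p = 0.00216. None of the 10 cell type lists passed; the lowest adjusted permutation p was 0.284.

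Per region, 0 of 48125 tested passed adjustment by Fisher's exact test (lowest adjusted p = 0.445), and at unadjusted p under 0.05 there were 227 higher in slow-biased and 1387 higher in fast-biased muscle (85.9% on the fast side). With the same number of peaks from each list 75.5% were on the fast side. Complete separation, 6 of 6 against 0 of 6, held for 234 regions, 18 of them on the slow side. At unadjusted Fisher's exact p under 0.05 Rora had 6 of the 277 regions of its locus on the fast side. Casq1, Runx2 (14.5 against 27.7 regions called in its locus), Fkbp5, a glucocorticoid target (10 against 15.3), Ppp3ca, a calcineurin subunit (14.7 against 24.2), Hdac4 and Myl4 (8.5 against 10) had 2 each. Myh4, Pgk1, Phka1, Ampd1 and Mylpf, the fast regulatory light chain (2.33 against 4.67), had 1. On the slow side Myoz2 had 2, and Atp2a2, Fnip1 (4 against 2.5), Meis1 (14.3 against 9.83), Comp (4.83 against 5.17), Itgam (3.67 against 4.5), Pdgfra (8.33 against 9.83), Col15a1 (20.3 against 23.2) and Eya1 (10 against 11.8) had 1, as did Sox6 in each direction. The direction of Comp, Col15a1 and Eya1 turned in at least 1 alternative. The fixed loci Myh1 (6 against 4.83), Myh3 (7 against 7.5), Myh8 (0.667 against 3.5), Tnnt1 (6 against 6) and Tnnt3 (4.67 against 5.67) had none. Neither had Tnni1 (8.33 against 10), Tnni2 (3.17 against 3.83), Myl2 (8 against 7.33), Myl3 (3.83 against 4.5), Atp2a1 (5.83 against 7) or Tbx15 (13.3 against 16).

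Separated regions of the adult slow-biased muscles (exact p = 0.00216, adjusted p = 0.445) lay on chromosome 9 at 31906111 to 31907437 inside Barx2, a homeobox gene of muscle progenitors. Others lay on chromosome 1 at 31011410 to 31013073 (61533 bp from Ptp4a1), on chromosome 11 at 17737411 to 17738134 (200619 bp from Etaa1), on chromosome 4 at 15595540 to 15596896 (284368 bp from Calb1) and on chromosome 15 at 61308342 to 61309592. Those of the fast-biased muscles lay inside Sorbs2 (chromosome 8, 45754953 to 45756234), Celf2, an RNA-binding protein (chromosome 2, 6950576 to 6951310), Fam83d (chromosome 2, 158780813 to 158782066) and Ctnnbl1 (chromosome 2, 157874926 to 157876222), and 65793 bp from Amigo2 (chromosome 15, 97177570 to 97178281). With calls that cover 50% of a region, the Barx2 region and those at 31011410 and 61308342 had an unadjusted Fisher's exact p of 0.182 and the Ctnnbl1 region 0.0606. With the first 57666 peaks of each list the region at 15595540 had 0.0606. Of regions higher in slow-biased and fast-biased muscle 11.9% and 13.2% lay within 1 kb of a gene end (Fisher's exact p = 0.67).

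At E18.5 the same comparison asked whether fibre bias is already visible in foetal muscle. The fast fibre list differed by -1.71 points between slow-biased and fast-biased muscle (random mean -1.55, permutation p = 0.9, adjusted p = 0.951) and the slow fibre list by 0.39 points (p = 0.148, adjusted p = 0.426). By muscle the fast list was called in 37.1 ± 6.12% of soleus, 36.3 ± 4.23% of vastus intermedius, 41.1 ± 8.3% of gastrocnemius and 35.7 ± 3.35% of vastus lateralis libraries (SD, n = 3). Without litter 1, within 1 date, the lists lay -0.224 and 1.95 points from random lists (adjusted permutation p = 0.977 and 0.598). Myh4 held 0.5 ± 0.837 against 0.667 ± 0.816 regions (n = 6 each), Sox6 20.3 ± 5.2 against 19.2 ± 5.34, and Atp2a2 9.5 ± 2.35 against 8.5 ± 1.38. Myoz2 held 0.667 against 0.667, Myh7 7.5 against 8.17 and Ppargc1a 24 against 20. No list or locus passed adjustment, and of the 414 loci 1 on each side had an unadjusted exact p under 0.05 (adjusted p = 1).

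Per region, 0 of 49906 tested at E18.5 passed adjustment by Fisher's exact test (lowest adjusted p = 1), with 118 higher in slow-biased and 294 in fast-biased muscle at unadjusted p under 0.05 and 4 and 22 separated completely. Without litter 1 or litter 3 the slow-biased count was 274 or 228, and without litter 2 the fast-biased count was 575. On the slow side Tnni2, Mef2a, a muscle transcription factor (10.3 against 9 regions), Notch1 (10.8 against 9.83), Lhx2 (8.33 against 8.67) and Rcan1 (13.5 against 14.7) had 1 region each at unadjusted p under 0.05. Tnni2 held 4 ± 1.26 against 2.67 ± 1.21. On the fast side Cx3cr1, a macrophage receptor (4.33 against 7), Hk2, a hexokinase (9.67 against 12.5), Zbtb16 (22.2 against 27.2) and Ly6a (2.83 against 3.33) had 1, as did Mcm5 (5.83 against 6.33), Arntl (21.3 against 22.2), Pfkfb3 (14 against 14.3), Kcnj8 (3.17 against 3.17) and Sox6. Myh2 (2.17 against 1.17), Myh1 (1 against 0.833), Myh3 (6.83 against 7.67), Myh8 (1.83 against 2), Tnnt1 (6.17 against 6), Tnnt3 (5.83 against 7.17) and Tnni1 (9.5 against 9.83) had none. Neither had Myl2 (7.67 against 7.83), Myl3 (4.5 against 4.67), Atp2a1 (6.67 against 7.67) or Tbx15 (10.5 against 10.7). Single regions with the lowest p lay inside Slc26a8 and Cfap43 on the slow side and inside Adamtsl1, Acoxl and Maml3 on the fast side, all with an adjusted p of 1 by Fisher's exact test. Each of these lost its unadjusted p under 0.05 in at least 1 alternative. Of regions on the slow and the fast side 7.63% and 12.6% lay within 1 kb of a gene end (Fisher's exact p = 0.169).

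The stages were compared for fibre bias in 3 ways. The fast fibre list differed more between slow-biased and fast-biased muscle in the adult than at E18.5, by -13.2 points where random lists averaged -2.94. The slow fibre list differed by 5.54 points where they averaged -3.1 (permutation against random lists, adjusted p = 0.00125 for each). With fibre labels permuted within animals, the same differences had exact p = 0.0216 (adjusted p = 0.514) and 0.153 (adjusted p = 0.514), so neither passed. That permutation exchanges muscles within animals and supposes no fibre difference in either stage. It compares with 0 and not with random lists, so it is not a test of equal differences with animals as the unit. The glycolytic list differed by -8.56 points (adjusted permutation p = 0.112) and the oxidative list by 0.421 (adjusted p = 0.27). The glycolytic difference passed in 7 alternatives (adjusted permutation p from 0.00167 with the same number of peaks from each list to 0.0275 without adult 1) and the oxidative one in 2 (0.0215 with the same number of peaks and 0.0467 without adult 3). With fibre labels permuted within animals neither passed (exact p = 0.0788, adjusted p = 0.514 for the glycolytic list, and 0.906, adjusted p = 0.944 for the oxidative list). Tested over both stages together, 0 of 159040 regions passed adjustment by the exact conditional test, and 1004 and 3999 were higher in slow-biased and fast-biased muscle at unadjusted p under 0.05. Among 13257 regions testable in both stages, fast-side regions numbered 302 in the adult and 69 at E18.5 and shared 3, where independent lists share 1.57 (Fisher's exact p = 0.208). The shared ones, named after the counts were seen and outside the rule for single regions, lay inside Fmnl1, inside Mpp3 and 5132 bp from Dchs2. Slow-side regions numbered 47 and 34 and shared 0, where 0.121 was the chance value.

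Pairs of muscles within a stage were compared to ask whether neighbouring slow-biased and fast-biased muscles differ more than muscles of like bias. Adult soleus and vastus lateralis were separated by 1754 regions called only in soleus and 4788 only in vastus lateralis (3 of 3 against 0 of 3), 6542 in all where the other splits of the 6 libraries averaged 3717. Soleus and gastrocnemius were separated by 1612 and 3442, vastus intermedius and vastus lateralis by 980 and 4297, and vastus intermedius and gastrocnemius by 897 and 3335. Muscles of like bias were separated by 2367 and 1459 regions (soleus and vastus intermedius) and by 1512 and 2227 (gastrocnemius and vastus lateralis). Slow-fast pairs of adult muscles averaged 5276 regions against 3306 in other splits, and pairs of like bias 3783 against 3308. At E18.5 the averages were 2999 against 3485 and 3065 against 3485, and soleus and gastrocnemius, for example, were separated by 687 and 2091 regions. These counts depend on list length. With the same number of peaks from each list, adult vastus intermedius was separated from vastus lateralis by 1464 and 1786 regions and from gastrocnemius by 1290 and 1515, so most of the excess on the fast side was lost. Soleus kept it, with 1235 and 3634 against vastus lateralis and 972 and 2802 against gastrocnemius, and soleus and vastus intermedius turned to 902 and 2018. Adult slow-fast pairs then averaged 3674.5 against 2161 in other splits and pairs of like bias 2657 against 2184. At E18.5 slow-fast pairs averaged 2217 against 2195 and pairs of like bias 2451.5 against 2199, with 2984 against 2138 for gastrocnemius and vastus lateralis. No region can reach a p under 0.1 with 3 against 3.

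**Figure D5:**
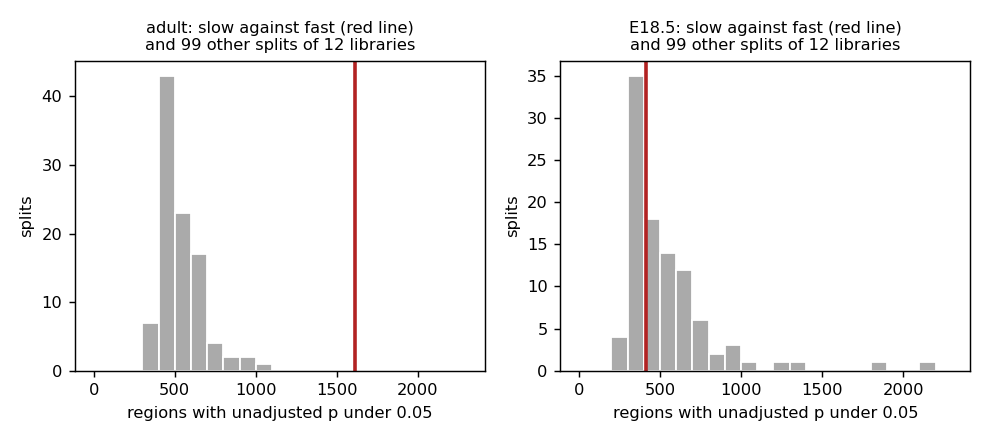
Number of regions at unadjusted Fisher's exact p under 0.05 (horizontal axis) in splits of 12 libraries of a stage into 6 and 6 (vertical axis, number of splits), with the real split of slow-biased against fast-biased muscles marked. The real adult split gave 1614 regions and other adult splits at most 1069, and the real E18.5 split gave 412 and another E18.5 split up to 2166.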

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

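The permutation within animals of the stage difference and the tests of explanations for it were chosen only after the result was seen. The test against random lists and its alternatives were planned, except for the same number of peaks from each list, which was added after the files were seen. The effect of fibre bias on the slow and the fast fibre lists differed between adult and E18.5 muscle by a test of the difference itself. Slow minus fast was 5.93 points in the adult and 0.39 at E18.5 for the slow fibre list, a difference of 5.54 points where random lists averaged -3.1. For the fast fibre list it was -14.9 and -1.71 points, a difference of -13.2 points where random lists averaged -2.94 (permutation against random lists, two-sided, adjusted p = 0.00125 for each). That test treats genes, not animals, as the unit. Permuting fibre labels within animals gave exact p = 0.153 for the slow list and 0.0216 for the fast list, both with an adjusted p of 0.514. That permutation exchanges muscles and supposes no fibre difference in either stage, so it does not have animals as the unit either. With 3 adults against 3 litters no permutation of animals can go below p = 0.1. These data therefore do not establish the difference between stages at the level of animals.

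Scatter between litters could hide a difference at E18.5, where the share of the fast list varied more between libraries of 3 muscles (SD 8.3 in gastrocnemius, 6.12 in soleus and 4.23 in vastus intermedius, against 3.93, 1.22 and 0.555 in the adult) and not in vastus lateralis (3.35 against 3.53). For the fast list, slow minus fast was -18.1, -13.6 and -13 points in the 3 adults and -5.87, 1.03 and -0.274 in the 3 litters (SD 3.66), so the litter closest to the adults lay further from them than this SD. Relative to all genes it was -10.5 to -11.3 in adults and -5.37 to 3.9 in litters (SD 4.64), again apart by more than the SD. No litter reached the adult values. With 3 litters and a limit set after the result was seen, this cannot exclude scatter, and the permutation within animals did not pass. For the slow list scatter stays open too: the values were 3.59 to 7.72 in adults and -3.92 to 7.69 in litters, which overlap, though relative to all genes they were 8.76 to 11.2 and 1.28 to 1.58. Weaker signal in all E18.5 lists was not tested. Complete mixing of muscles in dissecting the small E18.5 limb would leave no similarity by muscle, and with lists of equal length the index of the same muscle was higher by 0.0117 (exact permutation, one-sided p = 0.00174). With the full lists, as planned, it was 0.404 against 0.401 (exact p = 0.139), and it was higher by 0.0203 with the first 57666 peaks and by 0.0083 with 50% cover (exact p = 0.00174 for each), which argues against complete mixing and leaves partial mixing open. Without litter 1, which has its own date, the fast list lay -0.224 points from random lists. Litters 2 and 3 went opposite ways relative to all genes (-5.37 and 3.9), and neither reached the adult values. A mean over litters that disagree cannot decide whether litter 1 hides a difference. A biological difference between the stages stays open as untested, and so does the difference of all dates between them.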

How the results depend on the processing

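The same number of peaks from each list was an alternative chosen only after the data were seen; all others were planned, and the motif alternatives were not run for lack of a genome. The call of the fast fibre list in the adult, and the calls of both fibre lists between adult and E18.5 muscle against random lists, held under every alternative run on them. Of the main values under alternatives 289 stayed on their side of the threshold or within 1.5 times, 39 moved further, 12 lost a call and 3 gained one; of the other values 3468 stayed, 522 moved, 47 lost and 9 gained a call and 19 changed direction. Of 105 pairs of a named locus and a comparison (a locus can count in each comparison) 43 changed the sign of their mean difference in at least 1 setting. None of these were among the 34 with an unadjusted exact p under 0.05 within a stage or animals fully apart between stages. For changes below the cause was not tested. Read depth was not used here, so how much of a missed call is depth was not tested.

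With the same number of peaks from each list the E18.5 similarity by muscle was 0.0117, adult-higher regions numbered 4106, adult fast-side regions 897, shared fast-side regions 1 and adult lists past the threshold 7. With the first 57666 peaks of each list the similarity was 0.0203, 6270 regions were higher in the adult and 13032 at E18.5, 764 were on the adult fast side at 5.87 times the other splits, 53 and 94 on the E18.5 slow and fast sides, slow-fast pairs of adult muscles reached 2.46 times their other splits (1.6 with full lists), and 0 fast-side regions were shared. Regions past the threshold, first minus second group, there were 1 at Tnnt3, -1 at Tnni1, -2 at Myl2 and 2 at Tead1 between stages and -1 at Comp between adult muscles.

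When a call had to cover at least 50% of the region, the E18.5 similarity by muscle was 0.0083, adult-higher regions 1632, adult slow and fast sides 97 and 530 at 4.82 times the other splits, E18.5 sides 58 and 74, and shared fast-side regions 0. Net regions were -1 at Tnni1, -1 at Prrx1 and 1 at Tead1 between stages, and -1 at Col15a1 and -1 at Eya1 between adult muscles. With autosomes alone the adult similarity by animal was 0.00378 (exact permutation p = 0.0694). Adjusted over all regions 1658 were higher in the adult and 4866 at E18.5. With the gene body plus 50 kb, 7 adult lists passed, Myh8 had a net 5 and Tnni1 -1. The wider Myh8 locus takes in all of Myh4, which had 5 regions higher in the adult. The net 5 therefore does not show that Myh8 itself changed direction. With gene ends within 2.5 kb the stage difference was -1.48 points (Fisher's exact p = 0.0944).

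With the animal as a replicate block, lists permuted within animals gave 7 adult lists, the slow fibre list had an adjusted exact p of 0.0992, and the oxidative list, at -0.533 points, lay below 0 (p = 0.769), since that test compares with 0 and not with random lists. The 7 were the fast fibre and glycolytic lists and 5 that did not pass against random lists (embryonic and neonatal, regulators, myogenic progenitors, circadian clock, glucocorticoid and atrophy). The block and the value compared with changed together. The 7 calls and the lost call of the slow fibre list therefore cannot be laid to the block alone. Permuted within animals, the differences between the stages in fibre bias lost their calls too (adjusted exact p = 0.514 for both fibre lists). With the block, the regions at unadjusted p under 0.05 again numbered 227 and 1387 in the adult and 118 and 294 at E18.5. At this number of libraries, the call patterns that pass 0.05 are the same with and without the block. The counts could therefore not change, and they do not show that the regions are robust to the block. List lengths without the block gave exact permutation p = 0.165 and 0.913.

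Leaving out each animal or litter in turn (without replicate 1, 2 or 3), adult-higher regions ranged from 1416 to 2075 and E18.5-higher ones from 2917 to 9043. The adult ratio to other splits ranged from 1.77 (without adult 3) to 2.57. E18.5 slow-side regions ranged from 89 to 274 and fast-side ones from 256 to 575, shared fast-side regions from 1 to 4 and shared slow-side ones from 0 to 1. Similarity by muscle in the adult ranged from 0.00892 to 0.0209, by animal from 0.00551 to 0.00883 in the adult and from 0.0151 to 0.0433 at E18.5. The stage difference near gene ends ranged from -3.51 to -0.282 points. Net regions ranged from -2 to 2 at Ppargc1b, -1 to 1 at Col15a1, -1 to 2 at Prrx1 and -3 to 1 at Tead1.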

Other observations

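The separation of animal means between stages, the tests of explanations for the excess on the fast side and for chromosome Y, and the splits of whole animals and within animals were chosen only after results were seen; the splits of libraries were planned. The unit here was the mean over the 4 muscles of each animal or litter. Of 414 listed genes 50 had every adult above every litter in called regions, and 59 had every litter above every adult. With 3 against 3, chance separates 10% of genes in both directions combined, so 10% is not the reference for either count alone. No share over all genes is given here, and random lists were also called less in the adult than at E18.5. Genes named here were chosen after their values were seen, and no group of them was tested. Higher in all 3 adults, the fatty acid transporter Cd36 held 10.2 ± 2.5 regions against 4.67 ± 0.804 (SD, n = 3 animals or litters), Ucp3, a mitochondrial carrier induced by fatty acids, 7.08 ± 0.52 against 4.83 ± 0.52, and lipoprotein lipase Lpl 5.83 ± 0.382 against 2.75 ± 0.5. Other genes of fatty acid use did not separate, such as Acadm (5.17 against 5), Hadha (6.08 against 6) and Fabp3 (4.5 against 4.5). Of the slow list, Myoz2 was at 3.17 ± 0.382 against 0.667 ± 0.144, Lmod2 at 5.92 ± 0.144 against 2.42 ± 0.764 and Csrp3 at 5.75 ± 0.433 against 2.83 ± 0.804. The ubiquitin ligases of muscle atrophy, Trim63 and Fbxo32, held 6.67 ± 0.764 against 3.92 ± 1.51 and 10.2 ± 1.73 against 7 ± 0.661, and the glucocorticoid target Tsc22d3 8 ± 1.39 against 3.92 ± 1.38.

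In all 3 litters above all 3 adults were 7 genes of the embryonic and neonatal list, among them the imprinted Meg3 (5.83 ± 1.44 against 11.1 ± 0.722), the RNA-binding protein gene Igf2bp1 (5.5 ± 0.901 against 8.83 ± 1.38) and the cardiac and foetal troponin Tnnt2 (6 ± 0.433 against 8.33 ± 0.52). The acetylcholine receptor subunit Chrna1 held 4.17 ± 0.382 against 8.33 ± 1.01, the proliferation marker Mki67 4.58 ± 0.52 against 8.08 ± 0.878, and the matrix gene Tnc 6.08 ± 0.382 against 10.9 ± 3.21. Of the Hox list 6 genes were separated this way, Hoxd13 with 3.67 ± 0.804 against 5.75 ± 0.25. Loci of this list share regions (183 counted over its genes, 106 of them distinct), so these genes are not all separate results. The lists of these genes other than the matrix list did not pass the test against random lists.

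For the 10371 regions between stages, 1 of 100 splits of the 24 libraries, the real one, gave as many, and the highest of the others gave 0. Such splits put libraries of one animal on both sides, so they do not exclude chance at the level of animals. Of the 10 splits of the 6 animals only the real one gave any (10371, highest other 0), and 10 splits are too few for a share under 0.05. In the adult the 1614 regions between slow-biased and fast-biased muscles were reached by 1 of 100 splits, the real one (highest other 1069), and at E18.5 59 of 100 splits gave at least the real 412. Those splits ignore that each animal or litter gave 4 muscles. Among splits that keep 2 muscles of each animal on each side, 1 of 100 in the adult, the real one, gave as many (highest other 1069). With 3 animals and 108 possible splits this makes chance unlikely there and does not exclude it. At E18.5 33 of 100 such splits gave at least 412 (highest other 785), so chance cannot be excluded. The highest free E18.5 split gave 2166 regions, several times the real count, and put all of litter 1 with 2 libraries of litter 2 on one side, which points to the litters as a structure of these samples. Without litter 1 the counts were 274 and 256. Over both stages the real count of adjusted calls was 0, which 100 of 100 splits reach by necessity (highest other 0), so the splits decide nothing there.

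For pairs of muscles 10 splits are too few for a share under 0.05. In the adult the real split ranked 1 of 10 for soleus and gastrocnemius (5054 regions, highest other 4738), soleus and vastus lateralis (6542, 4597), vastus intermedius and gastrocnemius (4232, 3489) and vastus intermedius and vastus lateralis (5277, 3462), 2 for soleus and vastus intermedius (3826, 3935) and 4 for gastrocnemius and vastus lateralis (3739, 4095). At E18.5 it ranked 8 for soleus and vastus intermedius (2362, 6021), 6 for soleus and gastrocnemius (2778, 7362), 7 for soleus and vastus lateralis (2884, 5841), 4 for vastus intermedius and gastrocnemius (3463, 7383), 7 for vastus intermedius and vastus lateralis (2871, 5545) and 2 for gastrocnemius and vastus lateralis (3768, 7291).

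Of the adult regions at unadjusted p under 0.05, 85.9% were on the fast side. Longer lists of fast-biased muscles do not account for all of it, since 75.5% were on the fast side with lists of equal length. A lower share of muscle nuclei in the slow-biased muscles would raise the markers of other cell types there, and the 9 lists of these lay -0.365 points from random lists on average, from -4.85 (tendon) to 3.41 (endothelium), which does not decide it. Less reproducible soleus lists may contribute: adult soleus had the lowest mean Jaccard index (0.313), and with lists of equal length vastus intermedius against vastus lateralis, which leaves soleus out, gave 1464 and 1786 separated regions, 54.95% on the side of vastus lateralis and only just under the limit of 55 set for this explanation. At the same length soleus and vastus intermedius, both slow-biased, gave 902 and 2018, and a biological difference of soleus stays open and was not tested.

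The 4 libraries of adult 1 held 263 to 441 peaks on chromosome Y, and those of adults 2 and 3 1930 to 2979. A female animal would lack Y genes, but all 4 libraries had a peak at Eif2s3y and 0 had one at Xist, the RNA of the inactive X. A lower yield over the whole of Y is not what the first 3.5 Mb show, where adult 1 averaged 29.5 peaks and adults 2 and 3 averaged 37.5 and 22.5, while beyond it, where Y is mostly repeated sequence, it had 240 to 400 peaks against 1911 to 2944. Reads of repeats may have been handled differently for libraries with that date, but animal and date coincide and cannot be told apart; in litter 1, the other replicate with its own date, 0.789% of peaks lay on Y, against 1.07% and 1.42% in litters 2 and 3. No biological explanation was tested.

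E18.5 gastrocnemius 2 overlapped the other muscles of litter 1 more (mean Jaccard index 0.479) than those of its own litter (0.432), and E18.5 soleus 2 did too (0.454 against 0.427). This was general to litter 1: 6 of the 8 libraries of litters 2 and 3 overlapped it more than their own litter, with vastus intermedius 2 (0.418 against 0.412), gastrocnemius 3 (0.4 against 0.366), vastus intermedius 3 (0.377 against 0.375) and vastus lateralis 3 (0.401 against 0.371). In the adult 2 of 8 did so for adult 1. Adult soleus 2 and 3 had the lowest mean index with the other libraries of their stage (0.301 and 0.306), and the other adult libraries ran from 0.327 to 0.357.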
